A study of Mus musculus with 12 samples.

How the data were processed

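The series holds 12 bulk RNA-seq libraries from mouse kidney, each from a separate animal of a model of contrast-induced acute kidney injury. Per the labels' protocols, male mice aged 8 weeks lost a kidney by surgery and recovered for 3 weeks. They were then kept from water for 24 h, received furosemide (a loop diuretic) 20 min before iodixanol (an iodinated contrast agent) was injected into the tail vein, and gave their kidney 24 h later. The labels place the libraries in 4 groups of 3, which form a first set (wild type and PAD4 knockout) and a second set (wild type and libraries labelled IL-33 knockout), each with its own wild-type libraries. No group without contrast injury is among the samples analysed here.

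The authors deposited FPKM values (fragments per kilobase of transcript, relative to all fragments mapped), as a table for each set with a column for each library, per the file headers. Per the labels' protocols, the libraries were poly(A)-selected and strand-specific. The submitters' processing notes name FastQC, cutadapt, HISAT2, StringTie, DESeq2 and edgeR, with no order and no version. The genome build and the annotation release are not given in the sources used here, so no coordinates are printed. The tables identify genes by Ensembl number only. A GENCODE mouse annotation gave symbols to 30212 of 32199 genes in the first table and 29690 of 31719 in the second, and it was used for symbols and for which genes overlap, not for positions. Of the genes listed for the IL-33 set, 1266 are at 0 in all 6 libraries, against 0 for the PAD4 set. Every column was mapped to a library or a group through its name, and 0 columns belonged to no sample. Wild-type columns of the second table carry the injury model's abbreviation and a number but no genotype, and were mapped because no other group of that set fits the name.

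FPKM does not carry sequencing depth. Ratios of low values between libraries did not pile up at those of whole reads (the fullest bin held 1.76% to 2.44% of the low genes, and 0.906% to 1.70% of genes of middle level), so the depth is unknown, and no interval or floor that needs it is given. FPKM summed to between 700601 and 812981 per library in the first table and between 385124 and 420279 in the second, and mitochondrially encoded genes took 52.0% to 60.0% and 24.1% to 29.2% of those sums. The tables were therefore treated as normalized separately, and no level was tested across them.

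Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), within each table, over genes with a mean FPKM of at least 0.5 in its 6 libraries. This left 13986 genes in the first table and 14513 in the second. Adjusted p values are from limma with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. All tests are two-sided. Changes are knockout minus wild type on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. Levels are means ± SD over the 3 libraries of a group unless marked SE. An SE beside a change with a limma adjusted p is limma's moderated one. It draws on the spread of other genes and can be smaller than the gene's own spread implies. With 3 libraries against 3, an exact permutation test cannot go below p = 0.1.

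The design, the other settings to be tried, 37 gene lists (cell types, pathways and markers of neighbouring tissues, from general knowledge) and the rule for naming genes were fixed before the data were examined. The rule names Padi4 and Il33, the 10 genes with the largest rise and the 10 with the largest fall that passed the threshold, had a mean FPKM of at least 1, an official-style symbol and no overlap between the groups, up to 4 members of each list (or 2 where none passed), and a set of injury, ferroptosis and neutrophil genes. For the joint comparison it names the 5 genes with the largest mean change in each shared direction and the 5 with the largest difference. Lists with at least 5 tested members were tested against the other genes with camera in limma, with its preset correlation of 0.01 between genes. Camera with a correlation estimated from the residuals and fry were run beside it. The difference between the changes of both comparisons was a contrast of 4 group means over all 12 libraries and the 13010 genes tested in both tables, and shared calls were compared with Fisher's exact test. Neither comparison uses the other's control libraries.

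Other settings chosen at that time were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 2, median-of-ratios scaling, rescaling of each library to the same sum (TPM), quantile normalization, eBayes with no trend, array weights, the replicate number as a block, each library left out in turn, and added thresholds of 2-fold. Lists of markers of 15 other tissues and cell types and 20 gene families were written after the first results had been seen. A score of RNA from other tissues was then added as a covariate for the PAD4 comparison. It is the mean log2(FPKM + 1) of the 34 colon, lung, uterus and heart markers with a mean FPKM of at least 1 in the first table and under 0.5 in the second. Also added after seeing the data were fits on genes that pass the filter in both tables, and fits with neither filter nor trend. Tables were prepared with Python 3.11.15 and the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.

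The steps were tested on simulated data with the real genes' means and spreads. In the PAD4 comparison (13986 genes), 38 of 100 genes simulated with a log2 change of 1 and 91 of 100 with a change of 2 were recovered, with 8 false among 137 calls. In the IL-33 comparison (14513 genes) the figures were 80 and 96, with 9 false among 185 calls, and for the difference (13010 genes) 36 and 91, with 3 false among 130 calls. The shifted gene list was called and 0 of 29 lists without a shift were called in both simulated comparisons. The simulated genes varied independently of each other, so this does not test the preset correlation between genes. Far fewer genes changed than were called in the real comparisons. The recovered and false calls therefore do not carry over to the real gene calls. Values of genes with near-identical copies (Hsd3b4 with Hsd3b2, Nat8f1 with its relatives, the globin pairs, Cyp4a12a with Cyp4a12b, Saa1) are uncertain, because how shared reads were divided is not given in the sources used here. The same holds for genes overlapping another on the same strand, among them Eif4ebp3, Ugt1a6a, Nnt, mt-Nd4l, Etfb, Bax, Itgam, Cd74, Pdgfra and Rhbg. The very short mt-Tg and Snora20 are uncertain as well in poly(A) libraries. The single-gene result of 1 gene of the lists is not reported here, while the gene stayed in every test.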

Results

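Kidney RNA was sequenced from 12 mice 24 h after injection of an iodinated contrast agent, which injures the remaining kidney in this model. The series was set up to ask how PAD4, the enzyme that citrullinates histones when neutrophils release extracellular traps, and the alarmin cytokine IL-33 bear on ferroptosis, an iron-dependent form of cell death, and on tubular injury. PAD4 knockout kidneys were set against 3 wild-type kidneys of their own set, and kidneys labelled IL-33 knockout against another 3, with 3 libraries in each of the 4 groups. Between 10205 and 11983 genes reached 1 FPKM per library in the PAD4 set and between 11765 and 12657 in the IL-33 set. Sequencing depth is unknown from FPKM values.

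Padi4 (ENSMUSG00000025330), the gene that encodes PAD4, was at 0.704, 1.06 and 1.67 FPKM in the wild-type libraries and at 0.217, 0.497 and 0.187 FPKM in the PAD4 knockout libraries, so transcript remained at 26.2% of the wild-type mean. The change was -0.71 ± 0.19 (SE), adjusted p = 0.0147, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allow. The limma call was lost without wild-type library 3 (adjusted p = 0.0752) and without PAD4 knockout library 3 (adjusted p = 0.059). It was also lost with no filter on level (adjusted p = 0.162), with no trend (adjusted p = 0.0579), with neither (adjusted p = 0.188) and with the score of RNA from other tissues as a covariate, where the change was -0.19 ± 0.34 (SE). Il33 (ENSMUSG00000024810) was at 1.71, 1.13 and 3.64 FPKM in the wild-type libraries of its set and at 1.14, 0.616 and 1.02 FPKM in those labelled IL-33 knockout. That difference did not pass the test (-0.65 ± 0.28 (SE), adjusted p = 0.099; exact permutation p = 0.2), except without wild-type library 2 (adjusted p = 0.035), under quantile normalization (adjusted p = 0.0395) and with the replicate number as a block (adjusted p = 0.0408). Values per gene do not tell which exons the remaining reads cover, so they do not settle the label, and "labelled IL-33 knockout" is used for these libraries. Il33 also fell in the PAD4 knockout, from 4.05 ± 1.09 to 1.25 ± 0.347 FPKM (-1.15 ± 0.23 (SE), adjusted p = 0.00208). Colon markers fell in 21 of 21 tested in the same comparison, so this fall of Il33 does not by itself show a change in kidney cells. Padi4 was at 0 to 0.0220 FPKM in the IL-33 set, below the level tested.

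**Figure D1:**
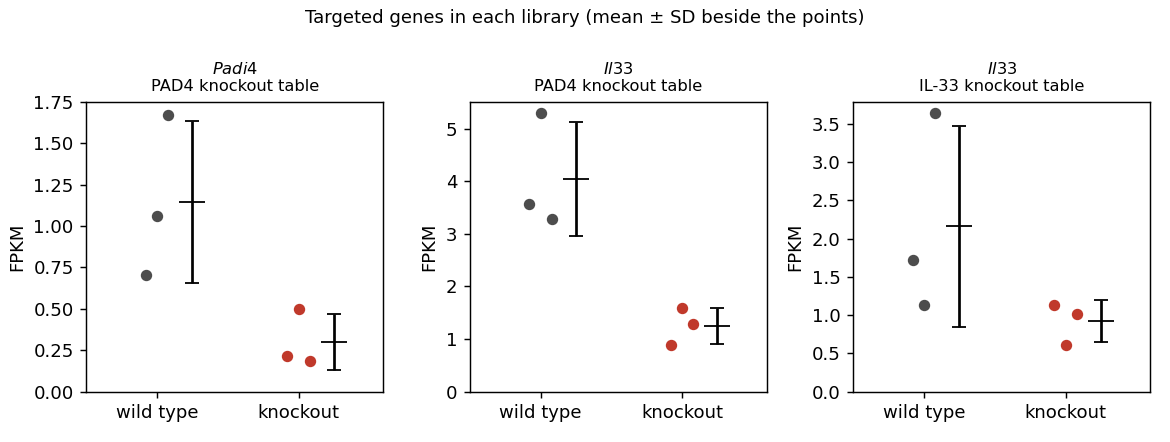
FPKM of Padi4 in the PAD4 set and of Il33 in both sets, with a point per library and the mean ± SD of the 3 libraries of each group. Il33 falls from 4.05 to 1.25 FPKM in the PAD4 set, while the libraries labelled wild type and IL-33 knockout overlap in the IL-33 set.

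In the PAD4 knockout kidneys, transcripts of the proximal tubule, thick ascending limb and intercalated cells and nuclear genes of oxidative phosphorylation were higher than in wild type, and transcripts of tubular injury, acute phase, immune cells and connective tissue were lower. These directions rest on camera with a preset correlation, and with an estimated correlation no list passed (smallest adjusted p = 0.501, with 1 list at an unadjusted p under 0.05). With a score of RNA from other tissues as a covariate, chosen after seeing the data, 11 lists passed with the preset correlation. The tubular injury, neutrophil and macrophage lists were not among them, and the thick ascending limb list turned lower. The largest rise was that of Ech1, a peroxisomal and mitochondrial enzyme of fatty acid breakdown, from 6.87 ± 0.278 to 361 ± 182 FPKM (n = 3 per group). Among the largest falls, Acsl4, which loads membrane lipids with the polyunsaturated fatty acids that ferroptosis oxidises, went from 27.01 ± 15.7 to 3.37 ± 1.03 FPKM. Markers of colon and lung, and those of smooth muscle, which kidney arteries hold too, fell along with the immune and connective tissue genes. Of 13986 genes tested with limma, 1243 rose and 1230 fell.

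Among the 10 largest rises, the changes were 5.41 ± 0.35 (SE), adjusted p = 5.4e-08 for Ech1, 4.09 ± 0.37 (SE), adjusted p = 3.97e-06 for Acadm and 3.68 ± 0.35 (SE), adjusted p = 5.18e-06 for Acadvl, both acyl-CoA dehydrogenases, and 3.96 ± 0.37 (SE), adjusted p = 4.82e-06 for Mdh1, the cytosolic malate dehydrogenase. Etfb, an electron carrier for those dehydrogenases, rose from 54.1 ± 8.84 to 432 ± 233 FPKM, and Cyb5a, cytochrome b5, from 14.97 ± 1.38 to 135 ± 55.9 FPKM. Keg1, Hsd3b4, Pcbd1 and Tmem174 completed the 10, with changes between 2.87 and 3.67. The largest fall was that of mt-Tg, a mitochondrial transfer RNA (-3.90 ± 0.39 (SE), adjusted p = 8.45e-06), whose level in poly(A) libraries is uncertain. Prap1 fell from 151 ± 78.6 to 16.9 ± 18.7 FPKM, the estrogen sulfotransferase Sult1e1 from 6.82 ± 2.55 to 0.203 ± 0.352 FPKM, the chemokine Cxcl14 from 27.9 ± 14.9 to 4.33 ± 2.81 FPKM and Serpina1e from 26.9 ± 14.5 to 4.58 ± 3.83 FPKM. Krt20, a keratin induced in injured tubules, fell from 57.6 ± 9.23 to 11.2 ± 11.1 FPKM, and Ltf, expressed in neutrophil granules and in the uterus, from 58.4 ± 33.9 to 11.95 ± 12.3 FPKM. Without wild-type library 1 neither passed (adjusted p = 0.0574 and 0.061). Sftpc and Scgb1a1, which encode secreted proteins of the lung, were among the 10 largest falls as well, from 154 ± 70.7 to 29.6 ± 27.2 FPKM and from 326 ± 186 to 60.4 ± 51.8 FPKM. Ltf, Prap1, Sftpc and Scgb1a1 are among the 34 markers in the score of RNA from other tissues, so the fall of Ltf does not by itself show a change in neutrophils. Krt20 is not among those markers, but colon markers fell in 21 of 21 tested. The fall of Krt20 thus does not by itself show less tubular injury.

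Of the proximal tubule markers, 18 of 28 tested members rose and 0 fell (20 and 0 adjusted over the list alone). The sulfate transporter gene Slc13a1 rose from 0.447 ± 0.171 to 5.65 ± 1.42 FPKM (2.18 ± 0.22 (SE), adjusted p = 9.32e-06), and the organic anion transporter genes Slc22a8 and Slc22a30 rose by 1.83 and 2.57. The list stood above the other genes (camera adjusted p = 1.17e-14, and adjusted p = 0.501 with an estimated correlation). In the thick ascending limb, 8 of 14 tested members rose and 0 fell (10 and 0 adjusted over the list alone, with camera adjusted p = 5.99e-06, and adjusted p = 0.525 with an estimated correlation). With the score of RNA from other tissues as a covariate this list turned lower (median -0.40, camera adjusted p = 0.00925, and 0.969 with an estimated correlation). Its member with the smallest p was Egf, from 0.974 ± 0.543 to 12.4 ± 9.901 FPKM (adjusted p = 0.00292, and 0.1 without wild-type library 1). Among markers of intercalated cells of the collecting duct, 6 of 14 tested members rose and 0 fell (9 and 0 adjusted over the list alone, with camera adjusted p = 4.33e-06, and adjusted p = 0.501 with an estimated correlation). The proton pump subunit gene Atp6v1b1 rose by 1.72, the alkali-sensing receptor gene Insrr by 1.69 and the ammonia transporter gene Rhbg by 1.43. Of the genes that androgens keep high in male kidney, 10 of 16 tested members rose and 0 fell (10 and 1 adjusted over the list alone, with camera adjusted p = 5.86e-06, and adjusted p = 0.501 with an estimated correlation). Several of the 16, Slc22a30 among them, are in the proximal tubule list too, so these lists are not separate evidence. Cyp4a12a (2.14, adjusted p = 4.11e-05) and Slco1a1 (0.99, adjusted p = 0.00109) were among those that rose. Xist, which is transcribed from the inactive X chromosome of females, went the other way, although the labels give males only. It was at 2.00, 1.78 and 4.97 FPKM in wild type and 0.401, 1.52 and 0.389 FPKM in the knockout. The distal convoluted tubule list, with 2 higher and 1 lower of 11 (3 and 1 adjusted over the list alone), did not pass (camera adjusted p = 0.0817). Nor did the principal cell list, with 3 and 0 of 14 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0875). It did pass without PAD4 knockout library 2 (adjusted p = 0.00982). In the same libraries the colon markers went the other way, with median FPKM of 25.4, 32.7 and 44.1 in wild type and 3.03, 13.1 and 7.26 in the knockout.

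Nuclear genes of oxidative phosphorylation rose by a median of 2.08. Of these, 18 of 26 tested members rose and 0 fell (19 and 0 adjusted over the list alone, with camera adjusted p = 1.17e-14, and adjusted p = 0.501 with an estimated correlation). The cytochrome c oxidase subunit genes Cox6a1 and Cox5b went from 79.5 ± 11.7 to 498 ± 238 FPKM and from 27.9 ± 4.85 to 187 ± 93.1 FPKM, and Sdhb, a subunit of succinate dehydrogenase, from 16.01 ± 4.42 to 105 ± 47.9 FPKM. The list of transcripts encoded in the mitochondrial genome, which does not hold mt-Tg, did not move with them. Of its 15 members, 1, mt-Nd4l, was higher (1 and 0 adjusted over the list alone), with a median of 0.077 and camera adjusted p = 0.786. In the list of fatty acid oxidation and PPAR-alpha targets, 9 of 28 tested members rose and 1 fell (9 and 1 adjusted over the list alone, with camera adjusted p = 0.000161, and adjusted p = 0.628 with an estimated correlation). Acadl went from 29.9 ± 2.87 to 159.8 ± 78.5 FPKM, and the member that fell was Pdk4, which restrains glucose oxidation (-1.68). The glycolysis list had 2 rises and 1 fall among 23 members (2 and 1 adjusted over the list alone; camera adjusted p = 0.98). The rises were those of Ldha, from 13.7 ± 3.61 to 75.9 ± 10.9 FPKM, and Aldoa, from 84.7 ± 4.64 to 412 ± 126 FPKM. Of the cholesterol synthesis genes, 2 of 21 tested members rose and 1 fell (4 and 2 adjusted over the list alone). The median was -0.019, the mean 0.15 and camera adjusted p = 0.713, and Hmgcs1 rose from 5.21 ± 1.96 to 44.1 ± 20.6 FPKM. The colon markers had a median change of -2.12 in the same comparison.

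Among tubular injury markers, 1 of 30 tested members rose and 18 fell (1 and 21 adjusted over the list alone, with camera adjusted p = 7.3e-09, and adjusted p = 0.501 with an estimated correlation). Cdkn1a, which encodes a cell cycle inhibitor, fell from 14.8 ± 0.842 to 3.67 ± 2.02 FPKM, and the fibrinogen chain genes Fgb and Fgg fell by 1.70 and 2.01 on the log2 scale. The member that rose was Clu, which encodes clusterin (1.19), named after its value was seen. The injury marker genes Havcr1 (KIM-1) and Lcn2 (NGAL) did not pass. Havcr1 was at 24.6, 10.9 and 25.9 FPKM in wild type and 0.885, 46.9 and 1.15 FPKM in the knockout (-1.80 ± 0.77 (SE), adjusted p = 0.114), and Lcn2 at 134 and 75.2 FPKM (-0.90 ± 0.37 (SE), adjusted p = 0.102). Havcr1 passed without PAD4 knockout library 2 (change of -3.32), without PAD4 knockout library 1 (-0.99, adjusted p = 0.0221) and without wild-type library 2 (-2.18). Without PAD4 knockout library 1, the knockout values left (46.9 and 1.15 FPKM) lay on either side of all wild-type values. That pass rests on limma's moderated error, not on separated groups. With the score of RNA from other tissues as a covariate Havcr1 rose (2.36, adjusted p = 0.00786). As a fall it also passed with a mean FPKM of at least 2, with TPM scaling, with the replicate block and on genes past the filter in both tables. Lcn2 passed under quantile normalization, with array weights and without PAD4 knockout library 1 (adjusted p = 0.014) or 2 (adjusted p = 0.0201). For complement and acute phase, 0 of 20 tested members rose and 13 fell (0 and 15 adjusted over the list alone, with camera adjusted p = 5.96e-10, and adjusted p = 0.501 with an estimated correlation). Saa1 went from 34.3 ± 9.71 to 7.904 ± 4.77 FPKM and Serpina3n from 14.7 ± 12.5 to 2.37 ± 1.22 FPKM. Immediate early genes, which respond within minutes to stimulation, showed 0 rises and 12 falls among 18 (0 and 15 adjusted over the list alone; camera adjusted p = 1.47e-07, and adjusted p = 0.501 with an estimated correlation). Among them were Klf4 (-1.68, adjusted p = 0.00287), Maff (-1.19, adjusted p = 0.00408) and Btg2 (-1.21, adjusted p = 0.00687). For p53 targets and cell death, 1 of 20 tested members rose and 7 fell (1 and 7 adjusted over the list alone, with camera adjusted p = 0.0325, and adjusted p = 0.628 with an estimated correlation). The member that rose was Bax, a pro-apoptotic gene, from 12.1 ± 2.696 to 53.8 ± 12.98 FPKM. The p53 list missed without wild-type library 1 (adjusted p = 0.0548), PAD4 knockout library 1 (0.0864) or PAD4 knockout library 3 (0.0624). Smooth muscle markers fell with these genes, from median FPKM of 26.8, 26.6 and 55.1 to 6.14, 18.7 and 9.96.

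Neutrophil markers fell, in that 0 of 15 tested members rose and 10 fell (0 and 11 adjusted over the list alone, with camera adjusted p = 1.82e-07, and adjusted p = 0.501 with an estimated correlation). Pglyrp1 went from 7.68 ± 2.44 to 1.73 ± 1.27 FPKM and the integrin gene Itgam from 1.83 ± 0.634 to 0.432 ± 0.333 FPKM. Ly6g, the marker used to count mouse neutrophils, went from 6.397 ± 3.02 to 2.07 ± 0.925 FPKM (adjusted p = 0.00597, and 0.051 without wild-type library 3). Of the granule and trap component genes, 0 of 15 tested members rose and 9 fell (1 and 10 adjusted over the list alone, with camera adjusted p = 5.86e-06, and adjusted p = 0.501 with an estimated correlation). Lyz2, also expressed by macrophages, was at 83.3 and 20.7 FPKM in wild type and knockout, and Chil3 at 12.4 and 2.04 FPKM. Mpo and Elane, which encode granule enzymes found on traps, were below the level tested in both groups. For macrophages and monocytes, 0 of 14 tested members rose and 7 fell (1 and 10 adjusted over the list alone, with camera adjusted p = 9.57e-05, and adjusted p = 0.525 with an estimated correlation). Examples were Ly6c2 (-0.92, adjusted p = 0.0035) and Fcer1g (-1.15, adjusted p = 0.00789). For T, B and NK cells, 0 of 6 tested members rose and 2 fell (0 and 2 adjusted over the list alone, with camera adjusted p = 0.00595, and adjusted p = 0.501 with an estimated correlation). Gzma, of cytotoxic cells, fell by 0.79 on the log2 scale. In the same kidneys the lung markers had median FPKM of 7.49, 11.05 and 11.6 in wild type and 0.7899, 5.16 and 0.753 in the knockout. Those of antibody-secreting plasma cells were at 1.97, 2.83 and 4.21 and at 1.27, 1.97 and 1.71.

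Type I interferon genes showed 0 rises and 9 falls among 27 (0 and 14 adjusted over the list alone; camera adjusted p = 3.5e-07, and adjusted p = 0.525 with an estimated correlation). Examples were Oas1a (-1.21, adjusted p = 0.00361) and Zbp1 (-1.10, adjusted p = 0.0039). In the NF-kB and cytokine list, 0 of 21 tested members rose and 9 fell (0 and 12 adjusted over the list alone, with camera adjusted p = 5.36e-07, and adjusted p = 0.525 with an estimated correlation). With the score of RNA from other tissues as a covariate this list turned higher (median 0.40, camera adjusted p = 0.024, and 0.969 with an estimated correlation). Examples were Casp1 (-1.24, adjusted p = 0.00102) and Ccl7 (-1.01, adjusted p = 0.00361). Antigen presentation genes showed 0 rises and 4 falls among 19 (0 and 4 adjusted over the list alone; camera adjusted p = 7.01e-05, and adjusted p = 0.532 with an estimated correlation). They include Cd74, from 66.4 ± 16.7 to 25.1 ± 7.75 FPKM (adjusted p = 0.00836, and 0.0597 without wild-type library 3). Of the fibroblast and matrix genes, 0 of 21 tested members rose and 19 fell (0 and 21 adjusted over the list alone, with camera adjusted p = 1.65e-13, and adjusted p = 0.501 with an estimated correlation). Dcn went from 34.3 ± 6.004 to 7.42 ± 3.55 FPKM, Pdgfra from 6.15 ± 2.78 to 1.4996 ± 0.552 FPKM and the smooth muscle gene Tagln from 146 ± 65.8 to 31.6 ± 24.04 FPKM. Colon markers fell in 21 of 21 tested, smooth muscle markers in 9 of 10 and lung markers in 9 of 12 (with 1 higher). Uterus and oviduct markers fell in 7 of 13 and plasma cell markers in 6 of 9. Wild-type library values of the score of RNA from other tissues were 3.91, 4.44 and 4.68, and knockout values were 1.84, 3.56 and 2.35. PAD4 knockout library 2, with the score of 3.56, correlated with the wild-type libraries at 0.930 to 0.940 and with the least similar library of its own group at 0.935.

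Podocyte, endothelial and red blood cell lists stood below the other genes with camera adjusted p = 0.0369, 0.0352 and 0.00413. With an estimated correlation the adjusted p were 0.525, 0.708 and 0.525. Of the podocyte markers, 0 of 8 tested members rose and 1 fell (0 and 1 adjusted over the list alone). Of the endothelial markers, 0 of 16 tested members rose and 0 fell (0 and 0 adjusted over the list alone), and of the red blood cell genes, 0 of 8 tested members rose and 5 fell (1 and 6 adjusted over the list alone). Leaving out wild-type library 2 ended all 3 calls (adjusted p = 0.0993, 0.829 and 0.0693), as did leaving out PAD4 knockout library 2 (0.0673, 0.106 and 0.0905). PAD4 knockout library 1 carried the first 2 as well (without it, 0.166 and 0.216), and wild-type library 1 the red blood cell call (0.0567). The cell cycle list also stood below the others (camera adjusted p = 0.00227, and adjusted p = 0.628 with an estimated correlation). Of the cell cycle genes, 0 of 20 tested members rose and 0 fell (0 and 0 adjusted over the list alone). The lists of stress responses did not pass. They were those of the unfolded protein response (1 higher and 0 lower of 22; 1 and 0 adjusted over the list alone), with camera adjusted p = 0.98, and of heat shock proteins (0 and 2 of 16; 0 and 2 adjusted over the list alone), with 0.646. The lists of NRF2 targets (4 and 2 of 22; 5 and 3 adjusted over the list alone) and water balance (4 and 3 of 20; 4 and 4 adjusted over the list alone) did not pass, with camera adjusted p = 0.522 and 0.567. Nor did circadian clock genes (2 and 3 of 18; 2 and 3 adjusted over the list alone; camera adjusted p = 0.784). In those lists Atf5 rose by 1.34 (adjusted p = 0.00287), and Hspb1 (-1.84, adjusted p = 0.00193) and Nfil3 (-1.29, adjusted p = 0.00287) fell. Markers of tissues next to the kidney did not pass either. Adrenal gland had 0 rises and 1 fall among 6 (0 and 1 adjusted over the list alone; camera adjusted p = 0.181). Adipose tissue had 0 and 1 among 11 (0 and 1 adjusted over the list alone; camera adjusted p = 0.713). It did pass without PAD4 knockout library 1 (adjusted p = 0.00439) or 3 (adjusted p = 4.34e-05).

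Of the ferroptosis drivers and markers, 2 of 22 tested members rose and 7 fell (3 and 8 adjusted over the list alone, with camera adjusted p = 0.0118, and adjusted p = 0.601 with an estimated correlation). The change of Acsl4 was -2.57 ± 0.34 (SE), adjusted p = 0.000115, and Alox5ap, which activates 5-lipoxygenase, went from 5.43 ± 1.405 to 1.497 ± 0.831 FPKM. In the ferroptosis defence list, 2 of 22 tested members rose and 6 fell (2 and 6 adjusted over the list alone, with camera adjusted p = 0.33). Gpx4, the lipid peroxide reductase that holds ferroptosis back, was at 147 ± 19.1 FPKM in wild type and 139 ± 57.2 FPKM in the knockout (-0.15 ± 0.35 (SE), adjusted p = 0.836). Neither the transferrin receptor gene Tfrc (-0.14, adjusted p = 0.774) nor Ncoa4, the ferritin receptor (0.13, adjusted p = 0.798), nor heme oxygenase Hmox1 (-1.09, adjusted p = 0.157) passed. Hmox1 did pass with array weights and without PAD4 knockout library 1 (adjusted p = 0.000235) or 2 (adjusted p = 0.00051). Slc7a11 was below the level tested, at 0.394 and 0.159 FPKM. Of the IL-33 and ST2 signalling genes, 0 of 12 tested members rose and 3 fell (0 and 3 adjusted over the list alone, with camera adjusted p = 0.00595, and adjusted p = 0.525 with an estimated correlation). The epidermal growth factor receptor ligand gene Areg went from 1.75 ± 0.283 to 0.395 ± 0.443 FPKM. Il1rl1, which encodes the IL-33 receptor ST2, was below the level tested (0.05198 and 0.0161 FPKM in wild type and knockout). Heart markers, with 1 of 8 lower, had median FPKM of 2.44, 3.92 and 7.26 and 1.06, 4.81 and 1.67 in the same libraries.

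Of the 2473 genes that changed, 1261 did so by at least 2-fold, and 4609 genes (33.0%, against 10% by chance) had no overlap between the groups. The count was 1102 without wild-type library 1 and 1322 without wild-type library 3. Rises were then 357 and 792 and falls 745 and 530, and falls were 785 without PAD4 knockout library 3. With the score of RNA from other tissues as a covariate, chosen after seeing the data, 140 genes passed (112 higher, 28 lower) and 99 of the 125 named genes lost their call. In that fit 11 lists passed camera with the preset correlation. With no filter on level 0 passed in limma, with 6053 at an unadjusted p under 0.05.

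**Figure D2:**
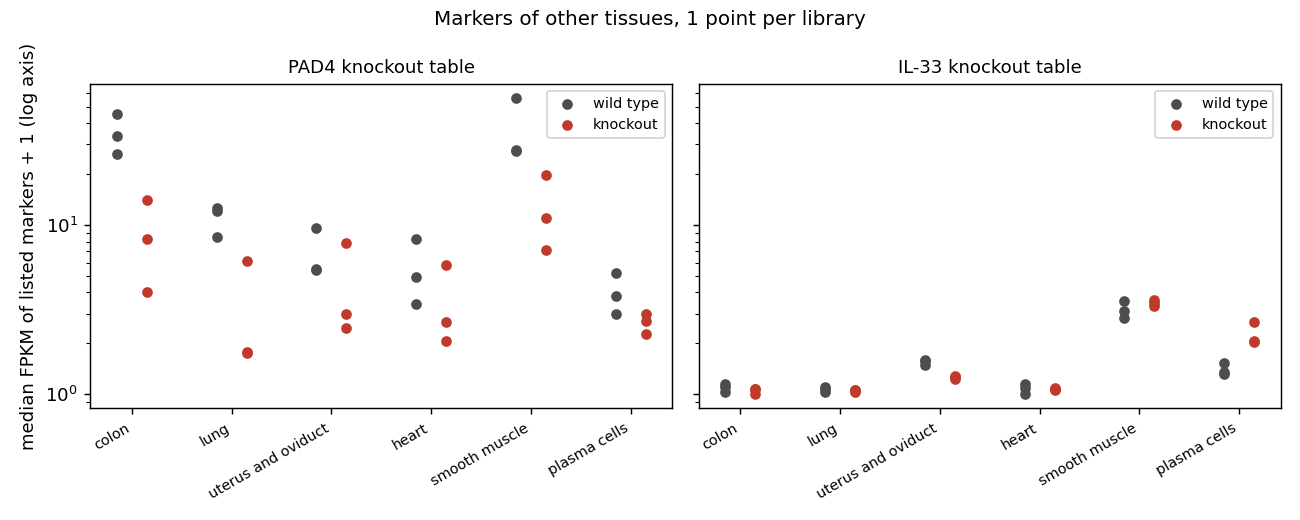
Median FPKM of marker genes of colon, lung, uterus and oviduct, heart, smooth muscle and plasma cells in each library of both sets, on a log axis. Colon markers run from 25.4 to 44.1 in the wild-type libraries of the PAD4 set and from 3.03 to 13.1 in its knockout libraries, and reach at most 0.144 in the IL-33 set.

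Kidneys labelled IL-33 knockout had lower transcripts of tubular injury, immediate early response, NRF2 targets and fatty acid oxidation than wild type, and higher transcripts of cholesterol synthesis and of nephron segments other than the principal cells. Set against the other genes with camera, these directions too rest on the preset correlation (smallest adjusted p = 0.384 with an estimated one). Fry, which does not set members against other genes, called these lists as well (adjusted p from 0.00252 to 0.0202). Krt20 went from 211 ± 147 to 0.321 ± 0.0717 FPKM (n = 3 per group), and the injury marker genes Lcn2 from 376 ± 203 to 19.1 ± 4.401 FPKM and Havcr1 from 108 ± 46.1 to 15.5 ± 10.2 FPKM. The endocytic receptor gene Lrp2 (megalin) of the proximal tubule went from 8.43 ± 1.82 to 69.1 ± 9.23 FPKM. Of 14513 genes tested with limma, 3226 rose and 2445 fell.

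**Figure D3:**
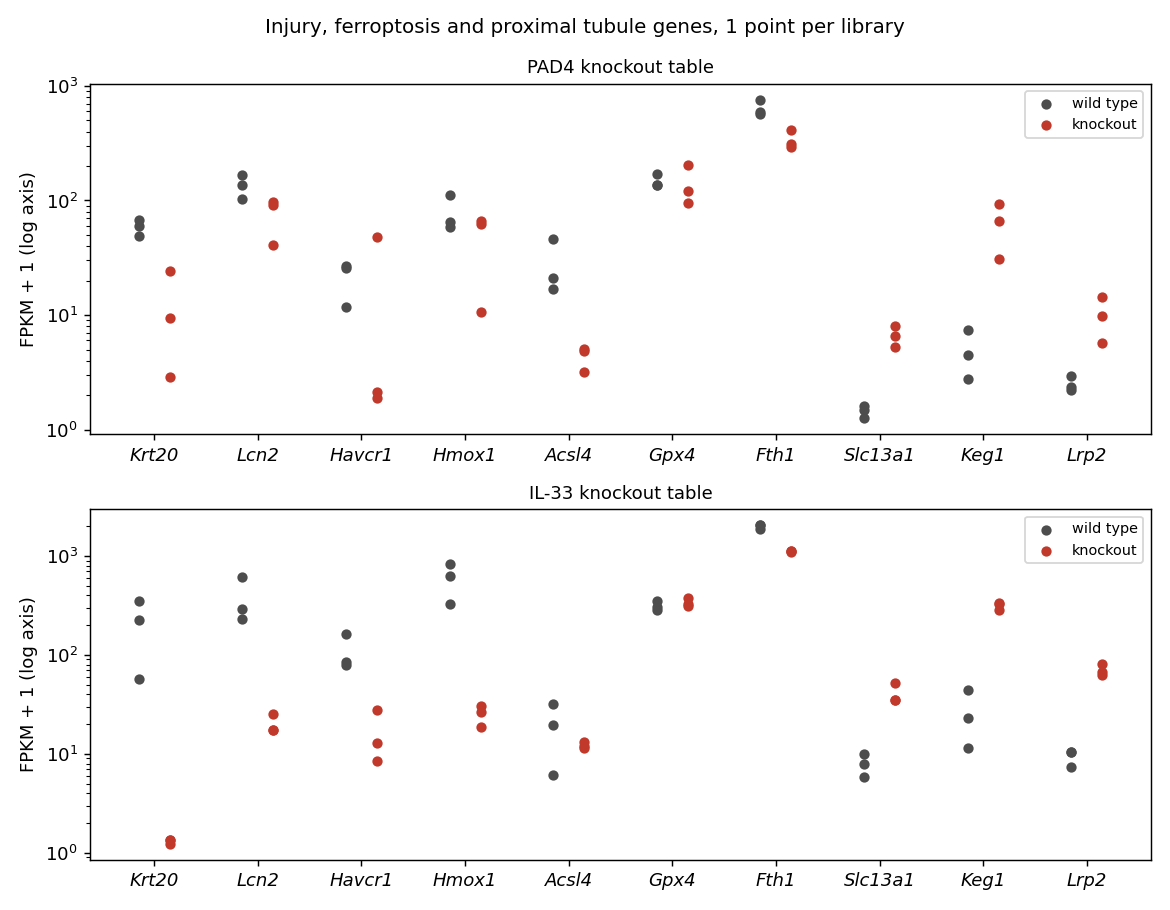
FPKM + 1, on a log axis, of injury, ferroptosis and proximal tubule genes in each of the 12 libraries. In the IL-33 set Krt20 goes from a mean of 211 to 0.321 FPKM and Lrp2 from 8.43 to 69.1, while Gpx4 does not pass the test in either set.

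Among genes with official-style symbols, the largest rise was that of Hsd3b4, a 3-beta-hydroxysteroid dehydrogenase, from 1.68 ± 0.408 to 203 ± 10.99 FPKM (6.26 ± 0.13 (SE), adjusted p = 3.06e-07), and its close relative Hsd3b2 rose from 0.396 ± 0.142 to 32.5 ± 5.71 FPKM. Gatm, which makes the precursor of creatine, rose from 4.02 ± 0.392 to 147 ± 45.6 FPKM (4.83 ± 0.23 (SE), adjusted p = 1.82e-05), Acmsd, an enzyme of tryptophan breakdown, from 0.501 ± 0.1602 to 20.2 ± 5.64 FPKM, and the transporter gene Slc7a12 from 0.173 ± 0.152 to 26.4 ± 16.5 FPKM. Fam151a, Nccrp1, Nat8f1, Keg1 and Sostdc1 rose by 3.78 to 4.50. The largest falls were those of Krt20 (-6.97 ± 0.58 (SE), adjusted p = 0.000149), Pdk4 (-6.22 ± 0.16 (SE), adjusted p = 1.29e-06) and Plin2, which coats lipid droplets (-5.56 ± 0.11 (SE), adjusted p = 3.06e-07). Hmox1, which breaks down heme, went from 594 ± 256 to 24.4 ± 5.95 FPKM, the stress cytokine gene Gdf15 from 156 ± 41.6 to 6.18 ± 1.76 FPKM, the endotoxin co-receptor gene Cd14 from 107 ± 24.02 to 4.46 ± 0.866 FPKM and the kinase gene Plk3 from 69.5 ± 16.97 to 2.64 ± 0.113 FPKM. Sult1e1 was at 36.3 ± 18.1 FPKM in wild type and is listed at 0 in the 3 libraries labelled knockout. Eif4ebp3 (-5.47), whose reads overlap another gene, and the antisense gene Slc6a19os (-4.52) were also among the 10.

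Tubular injury markers showed 1 rise and 22 falls among 29, with a median of -2.54 (1 and 22 adjusted over the list alone; camera adjusted p = 3.6e-11, and adjusted p = 0.384 with an estimated correlation). Lcn2 changed by -4.12 ± 0.34 (SE), adjusted p = 0.000144, and Havcr1 by -2.83 ± 0.44 (SE), adjusted p = 0.00212. Tnfrsf12a went from 179.9 ± 38.3 to 10.6 ± 0.872 FPKM and clusterin, Clu, from 419 ± 3.03 to 130.5 ± 8.02 FPKM. Immediate early genes fell in 18 of 18 (0 and 18 adjusted over the list alone; camera adjusted p = 1.05e-10, and adjusted p = 0.384 with an estimated correlation). Maff was at -3.45, Junb at -2.47 and Ier2 at -2.38. Of the NF-kB and cytokine genes, 0 of 13 tested members rose and 8 fell (0 and 10 adjusted over the list alone, with camera adjusted p = 9.2e-06, and adjusted p = 0.384 with an estimated correlation). The neutrophil chemokine gene Cxcl1 went from 14.01 ± 8.96 to 0.2904 ± 0.0255 FPKM and Il34, a growth factor of macrophages, from 77.2 ± 18.3 to 9.85 ± 2.002 FPKM. In the p53 and cell death list, 1 of 20 tested members rose and 7 fell (1 and 8 adjusted over the list alone, with camera adjusted p = 0.00606, and adjusted p = 0.384 with an estimated correlation). Cdkn1a went from 44.1 ± 18.3 to 2.41 ± 0.305 FPKM. The unfolded protein and integrated stress response list had 5 rises and 10 falls among 22 (5 and 10 adjusted over the list alone; camera adjusted p = 0.0258, and adjusted p = 0.654 with an estimated correlation). Among them Ddit4 fell (-1.66, adjusted p = 3.02e-05) and the chaperone gene Calr rose (1.48, adjusted p = 0.000286). Heat shock protein genes moved both ways, 5 up and 3 down of 16 (5 and 3 adjusted over the list alone; camera adjusted p = 0.999).

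In the proximal tubule, 21 of 30 tested members rose and 2 fell (21 and 3 adjusted over the list alone, with camera adjusted p = 7.68e-07, and adjusted p = 0.452 with an estimated correlation). Lrp2 changed by 2.91 ± 0.17 (SE), adjusted p = 3.42e-05. The amino acid transporter genes Slc7a7 and Slc3a1 went from 4.24 ± 0.475 to 32.7 ± 6.58 FPKM and from 71.4 ± 4.92 to 207 ± 9.295 FPKM. In the thick ascending limb, 12 of 14 tested members rose and 0 fell (12 and 0 adjusted over the list alone, with camera adjusted p = 4.19e-05, and adjusted p = 0.511 with an estimated correlation). Examples were Egf, from 30.2 ± 7.46 to 170.2 ± 34.3 FPKM, and Ptger3, from 3.43 ± 1.07 to 23.5 ± 5.65 FPKM. In the distal convoluted tubule, 10 of 13 tested members rose and 0 fell (10 and 0 adjusted over the list alone, with camera adjusted p = 3.08e-05, and adjusted p = 0.384 with an estimated correlation). Examples were the calcium-binding protein gene Pvalb, from 0.782 ± 0.0551 to 11.5 ± 4.004 FPKM, and the sodium-calcium exchanger gene Slc8a1, from 1.98 ± 0.336 to 14.3 ± 2.596 FPKM. Intercalated cell markers showed 8 rises and 0 falls among 14 (8 and 0 adjusted over the list alone; camera adjusted p = 0.00199, and adjusted p = 0.475 with an estimated correlation). The anion exchanger gene Slc4a1 went from 0.543 ± 0.215 to 13.6 ± 1.66 FPKM. Podocyte markers showed 6 rises and 0 falls among 12 (6 and 0 adjusted over the list alone; camera adjusted p = 0.0272, and adjusted p = 0.654 with an estimated correlation). The nephrin gene Nphs1 rose (0.85, adjusted p = 0.00499), and the list missed without wild-type library 2 (camera adjusted p = 0.0667). Principal cell markers (3 of 14 higher; 3 and 0 adjusted over the list alone) did not pass (camera adjusted p = 0.101). They did without wild-type library 2 (0.0367), wild-type library 3 (0.049) or labelled knockout library 1 (0.0374). Androgen targets went 7 up and 4 down of 16 (7 and 5 adjusted over the list alone; camera adjusted p = 0.459). The water balance list went 8 up and 3 down of 21 (8 and 3 adjusted over the list alone; camera adjusted p = 0.101).

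Genes of cholesterol synthesis and of fatty acid oxidation moved in opposite directions. Of the cholesterol synthesis genes, 20 of 22 tested members rose and 0 fell (20 and 0 adjusted over the list alone, with camera adjusted p = 1.54e-10, and adjusted p = 0.384 with an estimated correlation). Cyp51 went from 8.92 ± 1.26 to 68.6 ± 3.99 FPKM and Idi1 from 3.87 ± 0.532 to 22.9 ± 2.08 FPKM. Of the fatty acid oxidation and PPAR-alpha targets, 3 of 29 tested members rose and 19 fell (3 and 20 adjusted over the list alone, with camera adjusted p = 3e-07, and adjusted p = 0.472 with an estimated correlation). Pdk4 went from 384 ± 60.1 to 4.18 ± 1.02 FPKM, the lipase inhibitor gene Angptl4 from 67.3 ± 11.5 to 5.65 ± 1.16 FPKM and the peroxisomal enzyme gene Ehhadh from 599.9 ± 29.7 to 199 ± 16.4 FPKM. In the adipose tissue list 0 rose and 3 of 8 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.00674, and adjusted p = 0.384 with an estimated correlation). Those that fell were Cidec, Plin4 and Pnpla2, which act on lipid droplets in other cells as well. Oxidative phosphorylation genes showed 13 rises and 0 falls among 26, with a median of 0.32 (15 and 0 adjusted over the list alone; camera adjusted p = 0.00319, and adjusted p = 0.71 with an estimated correlation). The list missed without wild-type library 3 (camera adjusted p = 0.0908). The 15 listed transcripts encoded in the mitochondrial genome, which leave out mt-Tg, showed 0 rises and 0 falls (0 and 0 adjusted over the list alone, with camera adjusted p = 0.879). Hypoxia and glycolysis genes showed 9 and 7 among 23 (10 and 8 adjusted over the list alone; camera adjusted p = 0.8).

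NRF2 targets fell, in that 1 of 22 tested members rose and 15 fell (1 and 15 adjusted over the list alone, with camera adjusted p = 2.03e-06, and adjusted p = 0.384 with an estimated correlation). Srxn1 went from 417 ± 114 to 28.02 ± 1.29 FPKM and Cyp2a5 from 786 ± 165 to 102 ± 5.09 FPKM. In the ferroptosis defence list 6 of 22 tested members rose and 10 fell (6 and 11 adjusted over the list alone, with camera adjusted p = 0.0272, and adjusted p = 0.48 with an estimated correlation). Falls were those of thioredoxin reductase Txnrd1, from 84.4 ± 9.096 to 23.4 ± 1.895 FPKM, and of Gclc, for glutathione synthesis, from 206 ± 13.98 to 105 ± 10.02 FPKM. Others were those of Aifm2, which regenerates ubiquinol, from 11.7 ± 0.4998 to 6.03 ± 0.342 FPKM, and of ferritin heavy chain Fth1, from 1979.9 ± 100.3 to 1113 ± 24.02 FPKM. The defence list missed without wild-type library 2 (camera adjusted p = 0.0767). Of the ferroptosis drivers and markers, 8 of 20 tested members rose and 4 fell (8 and 5 adjusted over the list alone). The median was 0.077, the mean -0.043 and camera adjusted p = 0.477. Hmox1 fell (-4.48 ± 0.33 (SE), adjusted p = 9.93e-05) and the transferrin receptor gene Tfrc rose from 14.1 ± 1.84 to 29.99 ± 0.916 FPKM (1.04 ± 0.11 (SE), adjusted p = 0.000368). Gpx4 (0.12, adjusted p = 0.458) and Ncoa4 (0.051, adjusted p = 0.792) did not pass. Nor did Acsl4 (-0.36, adjusted p = 0.609), except without wild-type library 2 (-1.03, adjusted p = 0.0108). Slc7a11 and Ptgs2 were below the level tested.

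Of the macrophage and monocyte markers, 9 of 13 tested members rose and 2 fell (10 and 2 adjusted over the list alone, with camera adjusted p = 0.00613, and adjusted p = 0.646 with an estimated correlation). Cd14 and Cd68 were those that fell. The complement gene C1qa went from 3.92 ± 1.12 to 18.04 ± 0.592 FPKM and Adgre1, which encodes F4/80, from 0.1598 ± 0.0404 to 1.51 ± 0.158 FPKM. Antigen presentation genes showed 9 rises and 0 falls among 19 (9 and 0 adjusted over the list alone; camera adjusted p = 0.0161, and adjusted p = 0.71 with an estimated correlation). Cd74 went from 23.2 ± 8.23 to 90.6 ± 7.15 FPKM. Type I interferon genes showed 13 rises and 0 falls among 25 (15 and 1 adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.71 with an estimated correlation). Bst2 went from 9.87 ± 3.26 to 30.6 ± 2.94 FPKM. Of the fibroblast and matrix genes, 10 of 19 tested members rose and 2 fell (11 and 3 adjusted over the list alone, with camera adjusted p = 0.0272, and adjusted p = 0.728 with an estimated correlation). Col6a1 went from 1.53 ± 0.638 to 9.95 ± 0.208 FPKM and Col1a2 from 2.12 ± 0.8995 to 8.84 ± 0.755 FPKM. Without wild-type library 2 the antigen presentation and fibroblast lists missed (camera adjusted p = 0.0901 and 0.0905). Red blood cell genes rose in 7 of 8 (8 and 0 adjusted over the list alone; camera adjusted p = 0.000878, and adjusted p = 0.475 with an estimated correlation). Hbb-bt went from 147 ± 34.9 to 335 ± 68.9 FPKM. Plasma cell markers moved the same way, 4 higher and 1 lower of 7, from median FPKM of 0.536, 0.359 and 0.319 in wild type to 1.07, 1.69 and 1.04.

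Few neutrophil markers reached the level tested. Of those that did, 1 of 6 tested members rose and 1 fell (1 and 1 adjusted over the list alone, with camera adjusted p = 0.951). S100a8 was at 1.15 and 1.37 FPKM in wild type and the libraries labelled knockout (0.19, adjusted p = 0.579). Of the granule and trap components, 2 of 8 tested members rose and 1 fell (3 and 2 adjusted over the list alone, with camera adjusted p = 0.961). Lcn2, which tubules also make, fell, and Lyz2 rose from 3.53 ± 1.995 to 18.5 ± 2.08 FPKM. Ly6g, Mpo, Elane and Il1rl1 were below the level tested. IL-33 and ST2 signalling genes showed 1 rise and 4 falls among 12 (1 and 4 adjusted over the list alone; camera adjusted p = 0.141). The adaptor gene Myd88 went from 13.2 ± 2.19 to 6.81 ± 0.655 FPKM. Complement and acute phase genes went 5 up and 7 down of 16 (5 and 7 adjusted over the list alone; camera adjusted p = 0.374). Fga fell from 189.9 ± 34.3 to 15.7 ± 3.402 FPKM. Endothelial markers (1 and 1 of 16; 0 and 0 adjusted over the list alone) did not pass (camera adjusted p = 0.609). Nor did the lists of cell cycle (4 and 1 of 13; 4 and 1 adjusted over the list alone) and circadian clock (7 and 5 of 19; 7 and 6 adjusted over the list alone), with camera adjusted p = 0.459 and 0.943. The T, B and NK cell list had Cd8a alone at the level tested (0.91), and the adrenal list had Star, Akr1b7, Fdx1 and Scarb1 (-0.12, -0.97, 0.091 and -0.44), so neither was tested as a list.

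Of the 5671 genes that changed, 1536 did so by at least 2-fold, and 7922 genes (54.6%, against 10% by chance) had no overlap between the groups. The count was 3678 without labelled knockout library 1 (2128 higher, 1550 lower) and 3731 without labelled knockout library 3 (2127 higher, 1604 lower). Camera called 24 of 37 lists in the PAD4 comparison and 21 of 35 in the IL-33 comparison, and 0 in either with an estimated correlation (smallest adjusted p = 0.501 and 0.384; with 1 list in each at an unadjusted p under 0.05). Fry, which asks whether members move on balance one way, called 0 (smallest adjusted p = 0.0835, with 10 lists at an unadjusted p under 0.05) and 21.

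**Figure D4:**
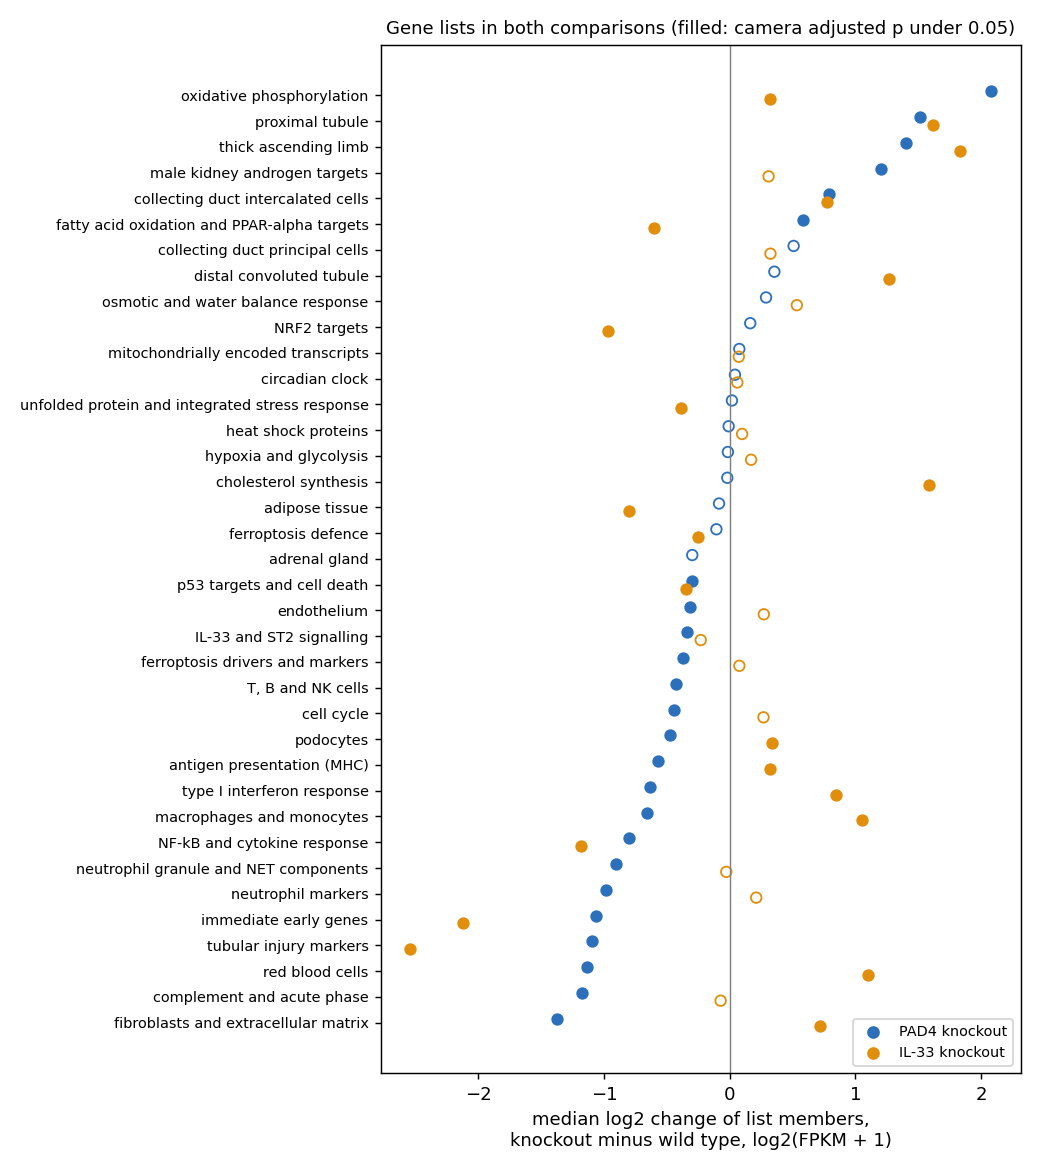
Median log2 change of the tested members of each gene list, knockout minus wild type, in the PAD4 and IL-33 comparisons. Tubular injury markers lie at -1.09 and -2.54, and oxidative phosphorylation genes at 2.08 and 0.32.

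The changes in both sets were compared over the 13010 genes tested in each table, with no control libraries in common. They shared 655 genes that rose in both, where independent lists would share 262 (Fisher's exact test, p = 1.73e-151), and 273 that fell in both, where 142 would be shared (p = 6.13e-31). Of the 1119 genes called in both, 928 (82.9%) had the same sign. Across genes the changes correlated with Pearson's r = 0.40 and Spearman's rho = 0.36. Genes are not independent replicates, so the p values of Fisher's exact test above do not measure the spread between animals. For r, 19 of 100 regroupings of the libraries, the real one included, gave a value as far from 0 in either direction (up to 0.61). Genes with the largest mean rise in both were Hsd3b4, Keg1, Nat8f1, Hsd3b2 and Nat8f6, of which Hsd3b4 and Hsd3b2 encode steroid dehydrogenases. Keg1 changed by 3.67 and 3.80. Those with the largest mean fall in both were Krt20, Pdk4, Sult1e1, mt-Tg and Plin2. Krt20 changed by -2.74 in the PAD4 comparison, where colon markers fell as well, and by -6.97 in the IL-33 comparison. The shared rises were 201 without wild-type library 1 and 433 without wild-type library 3 of the PAD4 set. The shared falls were 126 and 99 without those, 425 without PAD4 knockout library 2 and 127 without PAD4 knockout library 3.

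A contrast of the effects themselves passed for 1615 genes, 804 more positive in the IL-33 comparison and 811 in the PAD4 comparison. Fatty acid oxidation genes differed in 20 of 28, each more positive in the PAD4 knockout (median 0.58 against -0.69), as did 16 of 26 oxidative phosphorylation genes and 11 of 22 NRF2 targets (1 the other way). Cholesterol synthesis genes differed in 16 of 21, each more positive with IL-33 (median -0.019 against 1.55). Fibroblast and matrix genes (14 of 19), interferon genes (13 of 25), macrophage markers (9 of 12, with 1 the other way) and red blood cell genes (7 of 8) were likewise more positive there. Tubular injury markers differed in 13 of 29 as more negative in the IL-33 comparison and in 1, Timp2, the other way, and of the proximal tubule markers 2 and 4 of 28 differed. The colon, lung and smooth muscle markers that fell with the connective tissue genes in the PAD4 set were at median FPKM of 2.62 or less in every library of the IL-33 set.

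**Figure D5:**
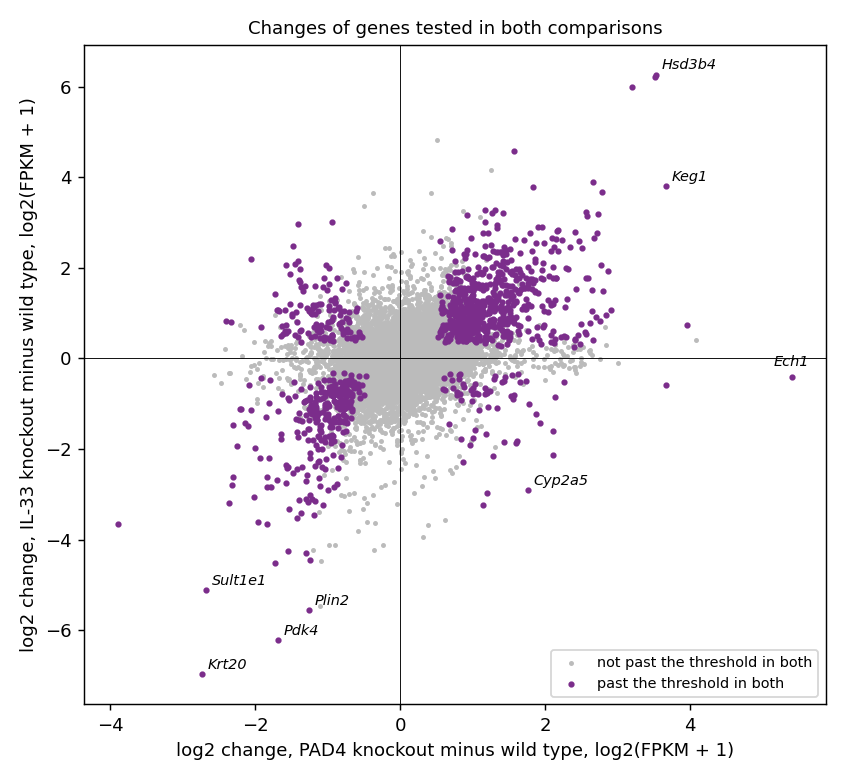
Log2 change in the PAD4 comparison (horizontal) against that in the IL-33 comparison (vertical) for the 13010 genes tested in both, knockout minus wild type. Krt20 lies low in both, at -2.74 and -6.97, and Ech1 lies at 5.41 and -0.41.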

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

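The tests of RNA from other tissues, scaling, dilution, transcript length, overlapping gene entries, strain and regrouped libraries in this part were chosen after the results had been seen, while the contrast of the changes of both comparisons was chosen earlier. That contrast, which asks whether a gene responded differently in the PAD4 and the IL-33 comparison, passed for 1615 of 13010 genes. The 5 genes with the largest difference, IL-33 minus PAD4, were all more positive in the PAD4 comparison. Ech1 differed by -5.82 ± 0.39 (SE), adjusted p = 4.03e-06, from a change of 5.41 in the PAD4 comparison and -0.41 in the IL-33 comparison. Cyp2a5, an NRF2-responsive cytochrome P450, differed by -4.69 ± 0.73 (SE), adjusted p = 0.00117 (1.77 and -2.91), and Pdk4 by -4.54 ± 0.42 (SE), adjusted p = 3.17e-05 (-1.68 and -6.22). The small nucleolar RNA gene Snora20, whose level in poly(A) libraries is uncertain, differed by -4.38 ± 0.39 (SE), adjusted p = 2.98e-05 (1.14 and -3.24). Eif4ebp3, which overlaps another gene, differed by -4.37 ± 0.51 (SE), adjusted p = 0.000234 (-1.11 and -5.47).

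The first pattern is the fall of immune and stromal genes in the PAD4 knockout, where 136 members of those lists had a median change of -0.90 and markers of colon and lung, and those of smooth muscle, which kidney holds too, fell with them. Scaling between libraries is argued against as its cause, since the highest median of the members under median-of-ratios, TPM and quantile scaling was -0.91. RNA from other tissues stays open and may account for much of it: with the score of such RNA in the model, the genotype coefficient of the members' mean went from -0.891 ± 0.275 to -0.147 ± 0.305 (SE), with a slope on the score of 0.423 ± 0.146, and it lost its call because the coefficient shrank while its error barely moved. The lung markers Scgb1a1 and Sftpc were at 326 and 154 FPKM in wild type, while in the kidneys of the IL-33 set 5 of 21 colon, 2 of 13 lung, 9 of 15 uterus and oviduct and 0 of 9 heart markers reached 0.5 FPKM. The PAD4 genotype itself stays open as well, because the score runs from 3.91 to 4.68 in the wild-type libraries and from 1.84 to 3.56 in the knockout libraries and so shares its variation with the genotype.

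The second pattern is the rise of nuclear oxidative phosphorylation genes in the PAD4 knockout, with a median of 2.08 over 26 members. Dilution of kidney RNA by other RNA in the wild-type libraries would raise kidney markers alike, and the 89 markers of all 6 nephron lists had a median of 0.72 (SD 0.913). Their medians ran from 1.51 for the proximal tubule, 1.40 for the thick ascending limb and 0.79 for intercalated cells to 0.51 for principal cells, 0.36 for the distal convoluted tubule and -0.48 for podocytes. The smaller rises among these do not decide against dilution, because log2(FPKM + 1) understates the change of markers at low FPKM. The marker Egf went from 0.974 to 12.4 FPKM, while the oxidative phosphorylation gene Cox6c lay higher, at 18.9 and 106 FPKM. That scale cannot turn a rise into a fall, so it does not account for the podocyte median of -0.48. Of 8 podocyte markers tested, 1 was called, as a fall. Dilution as part of the rise stays open, the proximal tubule markers being nearest to it. Whether dilution could be all of the rise is not settled, since the podocyte markers did not rise. A bias towards short transcripts is argued against by the 86 cytoplasmic ribosomal protein genes, with a median of -0.012 (SD 0.297), and scaling by the lowest median of the list under the other scalings, 1.80. With the score of RNA from other tissues as a covariate the median went from 2.08 to 1.10, and the list passed camera with the preset correlation (adjusted p = 5.82e-05) but not with an estimated one (adjusted p = 0.969, and 0.501 without the covariate), with 0 single members past limma's threshold and 888 genes in all at an unadjusted p under 0.05. The PAD4 genotype and a different share or state of the tubule segments rich in mitochondria stay open as hypotheses, and neither was tested further.

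The third pattern, singled out after its values were seen, is Nnt, the mitochondrial transhydrogenase gene, in the IL-33 comparison. The gene entry that rose changed by 3.65 ± 0.66 (SE) and the overlapping entry that fell by -2.83 ± 0.56. Reads divided between the overlapping entries may account for part of this, since the sum of both changed by 1.88 ± 0.25, from 7.16, 13.6 and 9.01 FPKM in the wild-type libraries to 38.8, 39.04 and 36.02 FPKM in those labelled knockout. In the PAD4 knockout libraries the entries traded places within the group. The entry that rose in the IL-33 comparison was at 0.124, 3.67 and 5.66 FPKM there, and the other at 18.4, 0 and 0 FPKM. A strain difference at Nnt, known to be partly deleted in some C57BL/6 substrains, cannot be told apart from the knockout, because values per gene do not show which exons the reads cover.

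Dividing the 6 libraries of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split gave 2473 genes in the PAD4 comparison, with at most 1 in any other split, and 5671 in the IL-33 comparison, with at most 0. Each other split mixes the groups, which puts any difference between them into the spread, so its low count says little. For gene lists, the real PAD4 split gave 24 and the other splits 9 to 24 (2 of 10 splits as large). The real IL-33 split gave 21 and the others 11 to 18 (1 of 10). Camera with the preset correlation thus called many lists in mixed splits as well. Regrouping the libraries within both tables gave as many shared calls as the real 928 in 1 of 100 regroupings, the real one, with at most 0 in any other. This decides nothing, because each other regrouping drawn called at most 1 gene in at least 1 of its tables and so had at most 1 to share. For the correlation of the changes, r = 0.40, 19 of 100 regroupings gave a value as far from 0 in either direction, with 0.61 the highest other, so chance cannot be excluded for it. As many differing genes as the real 1615 came in 2 of 100, and the highest other regrouping gave 2532. That regrouping mixed the PAD4 libraries and exchanged the labels of the IL-33 groups, which stayed whole. The same mix without the exchange gave 264. Exchanging the labels reverses the sign of each IL-33 change, and r was -0.48 with the exchange and 0.48 without it. Whether that accounts for the whole gap was not tested.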

How the results depend on the processing

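The covariate fit, the fits with neither filter nor trend and those on genes past the filter in both tables were chosen after the results had been seen, and the other settings were not. For the named genes, a reversal was counted where the direction flipped and either fit passed. A flip where neither fit passed was counted as unchanged. Under settings that keep all libraries, 3058 of the results were unchanged in that sense, 17 passed only there, 434 no longer passed and 14 reversed. With a library left out, 1600 were unchanged, 14 passed only there and 144 no longer passed. Pseudocounts of 0.1 and 0.5 moved no count by over 1.5 times, but at 0.1 the change of Padi4 was -1.64 and that of Il33 in the IL-33 comparison -1.02, since the pseudocount sets the scale of low values. Depth is unknown, so no limit that it sets can be given. Where no cause is named below, the cause was not tested.

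In the PAD4 comparison, no filter on level left 0 genes in limma, 0 higher and 0 lower, with 6053 at an unadjusted p under 0.05. Padi4 was at -0.71 there (adjusted p = 0.162), and 0 and 0 genes were shared higher and lower. Neither filter nor trend gave 11 genes (6 higher, 5 lower) and Padi4 at -0.71, and no trend alone gave Padi4 at -0.71 (adjusted p = 0.0579). A mean FPKM of at least 2, which tests fewer genes, gave 762 lower genes and 1011 that differed between the comparisons. Camera then called 19 lists in the PAD4 and 18 in the IL-33 comparison, against 24 and 21 in the main fit. It called 20 PAD4 lists under median-of-ratios scaling and 21 under quantile normalization. Median-of-ratios scaling gave 3041 that differed and 477 shared lower. Quantile normalization gave 1916 higher in the PAD4 comparison, 3069 that differed, 549 shared lower and Il33 in the IL-33 comparison at -0.74 (adjusted p = 0.0395). Array weights, whose estimation stopped before convergence, gave 5206 genes (2267 higher, 2939 lower) in the PAD4 comparison, 3525 that differed, and 993 and 695 shared higher and lower.

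Adding a 2-fold threshold, which by construction calls fewer genes, gave 1261 (676 and 585) in the PAD4 comparison, 1536 (897 and 639) in the IL-33 comparison and 261 and 118 shared. With an unadjusted p in its place the figures were 1306 (701 and 605), 1552 (901 and 651), and 268 and 129. Camera with an estimated correlation called 0 lists in the PAD4 and 0 in the IL-33 comparison (1 and 1 at an unadjusted p under 0.05), and fry called 0 in the PAD4 comparison (10 at an unadjusted p). The podocyte, endothelial, p53 and red blood cell lists of the PAD4 comparison lost their call under median-of-ratios scaling (adjusted p = 0.083, 0.125, 0.0588 and 0.0605), and the ferroptosis defence and unfolded protein lists of the IL-33 comparison did under quantile normalization (adjusted p = 0.115 and 0.0641).

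With the score of RNA from other tissues as a covariate, the PAD4 comparison gave 140 genes (112 higher, 28 lower), 11 lists with camera's preset correlation and Padi4 at -0.19. Of its named genes, these 14 reversed: Havcr1 to 2.36 (adjusted p = 0.00786), S100a8 to 0.54, S100a9 to 0.19, Alox15 to 0.0020, Retnlg to 0.21, Arg1 to 0.015, Trpm6 to 0.034, Aqp3 to -0.35, Cd14 to 0.17, Mpeg1 to 0.17, Il18 to 0.0022, Slc14a2 to -0.46, Agt to -0.021 and Akr1b8 to 0.33. The thick ascending limb list turned lower (median -0.40, camera adjusted p = 0.00925) and the NF-kB list higher (0.40, 0.024). Both calls rest on the preset correlation, and neither list passed with an estimated one. The score shares its variation with the genotype.

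Leaving out 1 library at a time, the PAD4 comparison gave 1102 to 3543 genes, 357 to 1788 higher and 530 to 1755 lower, 21 to 24 lists and Padi4 at -0.86 to -0.53. The lowest counts were 1102 and 357 higher without wild-type library 1 and 530 lower without wild-type library 3. The IL-33 comparison gave 3678 to 6092 genes, 2127 to 3851 higher and 1550 to 2670 lower, 18 to 22 lists and Il33 at -0.89 to -0.33. The lowest counts came without labelled knockout libraries 1 and 3 (3678 and 3731). Across both, 1082 to 1859 genes differed, and 201 to 924 and 99 to 425 were shared higher and lower, with r from 0.32 to 0.45. Fewer libraries leave fewer degrees of freedom.

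The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0159, -0.113 and -0.146 in the PAD4 set and -0.0144, 0.134 and -0.00166 in the IL-33 set. With the number as a replicate block, 1984 and 5336 genes passed, and Il33 in the IL-33 comparison, still at -0.65, passed (adjusted p = 0.0408).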

Other observations

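The gene families and tissue markers in this part were chosen after the first results had been seen, and the numbers in parentheses are rises, falls and camera adjusted p. In the PAD4 comparison, 50 of 69 immunoglobulin genes fell and 0 rose (median -0.92, camera adjusted p = 1.13e-25), and chemokine ligand genes showed 0 rises and 9 falls among 22 (5.47e-07). Keratins (0 and 5 of 13, 0.00859) and collagens (3 and 8 of 25, 0.0107) also stood below the other genes. Solute carriers stood above the other genes, with 78 rises and 24 falls among 272 (camera adjusted p = 0.000179), as did V-type ATPase subunits, with 8 and 0 among 22 (0.000118). Above them as well were glutathione transferases (6 and 1 of 21, 0.00657) and UDP-glucuronosyltransferases (5 and 2 of 12, 0.0268). Mitochondrial ribosomal proteins (4 and 0 of 80, 7.1e-06), histones (6 and 0 of 17, 0.00328) and Zfp zinc finger proteins (9 and 1 of 233, 0.042) stood above them too. With an estimated correlation the smallest camera adjusted p over the 20 families was 0.859. Families that did not pass were cytochrome P450 (13 and 10 of 46, 0.847), claudins (1 and 3 of 15, 0.581) and tubulins (0 and 4 of 18, 0.214). The same held for DnaJ proteins (3 and 0 of 38, 0.113), aldo-keto reductases (4 and 3 of 13, 0.402) and regulators of G-protein signalling (1 and 1 of 9, 0.0665). For cytoplasmic ribosomal proteins (86 genes, 0.825), proteasome subunits (37, 0.88) and vesicle coat and SNARE genes (19, 0.847) 0 members passed limma, and the sign of the median flipped with the scaling.

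In the IL-33 comparison, proteasome subunits fell in 20 of 37 with 0 rises (median -0.32, camera adjusted p = 1.45e-05). Cytoplasmic ribosomal proteins fell in 23 of 85 with 0 rises (median -0.17, 2.02e-05) and tubulins, which build microtubules, in 10 of 18 with 0 rises (median -0.83, 0.00213). Collagens showed 15 rises and 3 falls among 22 (median 0.93, 0.00392), and solute carriers 121 and 46 among 273 (0.000831). With an estimated correlation the smallest camera adjusted p over the 20 families was 0.267. Families that did not pass, with rises and falls, were mitochondrial ribosomal proteins (21 and 6 of 82, 0.175), cytochrome P450 (8 and 13 of 41, 0.145), UDP-glucuronosyltransferases (6 and 1 of 14, 0.0652) and keratins (1 and 4 of 11, 0.0652). Others were histones (1 and 1 of 19, 0.912), Zfp zinc finger proteins (40 and 18 of 271, 0.265), V-type ATPase subunits (7 and 2 of 22, 0.118) and DnaJ proteins (15 and 5 of 41, 0.11). The same held for aldo-keto reductases (7 and 3 of 13, 0.118), immunoglobulin genes (5 and 0 of 17, 0.0544) and regulators of G-protein signalling (2 and 1 of 9, 0.33). Claudins (5 and 4 of 14, 0.977) had a median of 0.12 where camera's direction was down. For glutathione transferases (4 and 8 of 21, 0.37), chemokine ligands (4 and 2 of 13, 0.898) and vesicle coat and SNARE genes (4 and 4 of 18, 0.782) the sign of the median flipped with the scaling.

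Of the other tissue marker lists, those of bone marrow (0 higher and 4 lower of 7 tested), small intestine (0 and 4 of 8), pancreas (0 and 3 of 4) and liver (1 and 3 of 10) were counted in the PAD4 comparison. So were those of stomach (1 and 1 of 3), skeletal muscle (0 and 1 of 4), skin (0 and 0 of 4), brain (0 and 0 of 1) and testis (0 tested). In the IL-33 comparison the counts were 0 and 3 of 5 for colon, 1 and 1 of 2 for lung and 2 and 3 of 9 for uterus and oviduct. They were 1 and 0 of 6 for smooth muscle, 4 and 2 of 7 for liver and 1 and 0 of 4 for bone marrow. For gut they were 0 and 0 of 5 for small intestine and 1 and 0 of 2 for stomach. They were 2 and 0 of 2 for pancreas, 1 and 0 of 1 for skeletal muscle and 1 and 1 of 5 for skin. For brain they were 0 and 0 of 1, for testis 1 and 0 of 1, and 0 heart markers were tested. In the IL-33 set Xist was at most 0.0151 FPKM, and the Y-linked gene Ddx3y was at 1.97 to 2.70 FPKM in the PAD4 set and 4.98 to 11.7 FPKM in the IL-33 set.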
